A study of Mus musculus with 12 samples.

How the data were processed

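Brown adipose tissue of mice was profiled by bulk RNA sequencing with a stranded mRNA kit, per the labels' protocols. The 12 libraries form 4 groups of 3, Flox and Nfe2l1(f)-KO at 4 weeks and at 14-16 weeks of age. The deposited values are raw read counts per gene in 2 tables, 1 for each age, and every value is a whole number. Per the submitters' processing notes the reads were mapped to GRCm38 and the tools were Trimmomatic 0.36, STAR 2.5.3a, featureCounts and Subread 1.5.1. How reads with several hits were handled, and whether the counting used strand, is not stated there, so reads of near-identical or overlapping genes cannot be told apart. Among counts from 1 to 20, 74.4% to 78.4% were even in each library, which would arise if both reads of a pair were counted. Counts are called reads here, and the number of sequenced fragments was not determined. The labels do not say whether the 3 libraries of a group came from separate animals, so each p-value measures the spread between these libraries.

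The table of the younger age held 53819 genes and that of the older age 49492, with 43329 symbols in both. Gene coordinates were compared with an annotation of GRCm38. For 99.9% of the matched symbols of the 14-16-week table the positions overlapped it, but for 10.6% of those of the 4-week table, so coordinates are printed from the 14-16-week table. Of the shared symbols, 37865 had the same chromosome and length in both tables and 9 lay on different chromosomes. Shared symbols held at least 96% of the reads of every 4-week library and at least 96.6% of those of every 14-16-week library. Both tables were joined on the symbol for the comparisons that use all 12 libraries. Age, table and annotation change together, so a difference between the ages cannot be told apart from one between the tables.

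Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr by group, library sizes were scaled by TMM, and groups were compared with the quasi-likelihood F test (robust fit). Adjusted p-values are Benjamini-Hochberg over all genes tested, with a threshold of 0.05. Libraries labelled KO were compared with Flox libraries within each age (6 libraries each). The genotype by age interaction and the 2 comparisons of the ages used a model of the 4 group means over all 12 libraries. The mean of the KO minus Flox differences over both ages was added after the data were examined. CPM values are read counts scaled to the TMM-adjusted library size, within the age for the KO comparisons and over all 12 libraries for the age comparisons, given as mean ± SD with n = 3. Log2 differences are the fitted ones, with their SE.

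Gene lists, 38 in all, were fixed in writing and tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over the 38 lists. Of these, 11 held markers of other cell types (macrophage, T cell, B cell, neutrophil, endothelial, adipocyte progenitor, mural, Schwann cell, skeletal muscle, blood and white adipocyte). The others held metabolic, stress and matrix programmes and signs of tissue handling. Each list was also tested with an estimated correlation and with fry, and its members were counted past the threshold over all genes and adjusted over the list alone. The groups, comparisons, lists, tests, alternatives and the rule for named genes were chosen before the data were examined.

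The rule named Nfe2l1, 27 marker genes whether or not they passed, and the largest changes among genes past the threshold whose groups did not overlap and whose mean was at least 10 CPM in the higher group. It took 6 genes per direction for the KO comparisons and 4 for the age comparisons, without predicted or unnamed genes and receptor segments. Up to 4 members past the threshold were to be named for each called list. As no gene passed at either age, members of lists and a few other genes are named as examples chosen after their values were seen.

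The alternatives were DESeq2 1.42.0, limma-voom, RLE and upper-quartile scaling, no filter except 1 read, a filter of CPM 1 in 3 libraries, a fold change of 1.5 as the null, a replicate block, mitochondrial genes left out, all 12 libraries in the fit, and each library left out in turn. Chosen after seeing the data were a skeletal muscle score as covariate, the fit without the 2 Flox libraries with Xist reads, the fit without mitochondrial genes, their nuclear copies and Rn18s, and genes of the same model in both tables. Where 1 library of a group remained, it was assumed to vary like the other groups. The muscle score is the mean, over the muscle markers, of log2 CPM centred on the libraries of the same age.

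The tests were tested on simulated data: counts drawn from the real means, library sizes and dispersions with 200 genes changed, 50 at each fold. For the 4-week comparison (20465 genes) 6%, 64%, 82% and 86% of genes changed 2-fold, 4-fold, 8-fold and 16-fold were recovered, and 7.75% of 129 calls were false. For the 14-16-week comparison (17962 genes) the shares were 2%, 44%, 68% and 90%, with 11.3% of 115 calls false. For the interaction (19140 genes) they were 0%, 22%, 58% and 68%, with 5.13% of 78 calls false. For age in Flox they were 6%, 42%, 78% and 84% (0.943% of 106 calls false), for age in KO 6%, 52%, 86% and 88% (4.92% of 122), and for the mean over both ages 24%, 88%, 94% and 96% (6.21% of 161), each over 19140 genes. All recovered genes had the simulated direction. A list shifted by 1 on the log2 scale was recovered by all 3 list tests in the 4-week, 14-16-week and interaction simulations. The preset test called 1 other list at 14-16 weeks. Each gene was drawn independently, while members of a real list can vary together. The simulations therefore do not show how often the list tests miss or miscall lists in the real data.

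Identical columns were looked for within each age, and 0 of 30 pairs were identical. Reads over a whole gene do not check the deleted part of Nfe2l1, and no read-level data were used here.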

Results

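Brown adipose tissue, the fat depot whose mitochondria burn fuel to make heat, was profiled in mice labelled Flox or Nfe2l1(f)-KO at 4 weeks and at 14-16 weeks of age, with 3 libraries in each of the 4 groups. Flox is the usual name of control mice that carry recombination sites without the recombinase. Nfe2l1 encodes NRF1, a transcription factor of the endoplasmic reticulum membrane that raises proteasome subunit genes when proteasome capacity falls. The comparisons ask what goes with the KO label at each age, whether this differs between the ages, and what differs between the ages within each label. At 4 weeks the Flox libraries held 54514548, 49927109 and 50278173 counted reads and the libraries labelled KO 53766365, 55780698 and 56906282. At 14-16 weeks the Flox libraries held 29883695, 27711683 and 30592702 and the libraries labelled KO 34113117, 37447086 and 32489940. Mitochondrially encoded genes took from 3.12% (KO replicate 2 at 14-16 weeks) to 14.1% (Flox replicate 1 at 14-16 weeks) of the reads. At 4 weeks, Flox replicate 3 held 24038 reads of Xist, the transcript of the inactive X chromosome, and 4 of the Y-linked Ddx3y. Flox replicate 2 held 6540 and 2027 reads of these genes, and each of the other libraries held more Ddx3y than Xist reads. By these reads, sex was not balanced between the labels at 4 weeks or between the ages in Flox. The interaction shares this limit.

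Nfe2l1 (GRCm38, chromosome 11, 96817414 to 96829968) had more reads in libraries labelled KO. At 4 weeks it measured 570, 282 and 424 CPM in the libraries labelled KO and 280, 261 and 211 CPM in the Flox libraries, with means of 425 ± 144 and 251 ± 35.7 (SD, n = 3 each; log2 difference 0.76, SE 0.28, adjusted p = 0.481). At 14-16 weeks it measured 855, 1080 and 469 CPM against 171, 197 and 212 CPM, with means of 801 ± 309 and 193 ± 20.6 (log2 difference 2.05, SE 0.36, adjusted p = 0.569). All 6 of 6 libraries labelled KO lay above the highest Flox library of their age. The mean difference over both ages was 1.40 (SE 0.23, adjusted p = 0.212). None of these passed in edgeR, while DESeq2 called the gene at 14-16 weeks (2.07, adjusted p = 0.000237) and over both ages (1.41, adjusted p = 2.63e-05). Without KO replicate 3 at 14-16 weeks the mean over both ages passed in edgeR too (1.53, adjusted p = 0.0267). A loss of the whole transcript would go with lower counts, so the gene goes against the label. Counts over the whole gene do not check the deleted part, and the labels do not name the deleted exons. The libraries are therefore called libraries labelled KO, and every direction in the text is that of the label.

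At 4 weeks, skeletal muscle transcripts were higher in libraries labelled KO, with all 23 muscle markers above 0 and a median log2 difference of 1.56. Myh4, a myosin heavy chain of fast fibres, measured 5080 ± 3260 against 1290 ± 139 CPM (SD, n = 3 each; log2 difference 1.98), and Acta1, skeletal alpha-actin, 448 ± 228 against 144 ± 22.7 CPM (1.63). Immediate early genes, which switch on within minutes of a stimulus or of tissue handling, had a median of 2.28 with 20 of 22 above 0. Among them were Fosb (5.64), Egr3 (5.05), Fos (4.22) and Nr4a1 (3.37). By camera at the preset correlation both lists rose (adjusted p = 5.39e-29 and 9.54e-13), and both calls were lost at adjusted p = 0.556 with an estimated correlation. Over all genes 0 members of either list passed, while 22 muscle markers and 9 immediate early genes passed adjusted over the list alone. The muscle score was -0.77, -0.66 and -0.62 in the Flox libraries and 0.35, 1.49 and 0.21 in the libraries labelled KO. Fos stood apart in KO replicates 2 and 3, at 282 and 205 CPM, against 4.2 CPM in KO replicate 1 and 2.33, 7.21 and 16.8 CPM in Flox.

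Markers of Schwann cells, which wrap the nerve fibres of the depot, fell as a list at 4 weeks (median log2 difference -0.46, 2 of 11 above 0, adjusted p = 0.000538). Adjusted over the list alone 6 of 11 passed, among them the myelin genes Pmp22 (-0.62), Mbp (-0.46) and Mag (-1.49), the regulator Sox10 (-1.18), and Egr2 at 4.67, which the immediate early list also holds. White adipocyte markers fell as a list (-0.42, 4 of 14 above 0, adjusted p = 0.00395), and 1 of them, the amino acid transporter Slc7a10 (-1.33), passed adjusted over the list alone. Adipocyte progenitor markers (-0.31, 3 of 16 above 0, adjusted p = 0.0204) and p53 and apoptosis genes (0.24, 16 of 21 above 0, adjusted p = 0.0162) passed as lists, with 0 members adjusted over the list alone. These 4 calls were lost at adjusted p = 0.556 with an estimated correlation. Proteasome subunits fell slightly as a list (-0.16, 7 of 40 above 0, adjusted p = 0.00929), as did extracellular matrix genes (median -0.35, mean -0.07, 9 of 34 above 0, adjusted p = 0.0223), and neutrophil markers rose (1.30, 9 of 9 above 0, adjusted p = 0.0162). These 3 had 0 members adjusted over the list alone and were lost at adjusted p = 0.885 with an estimated correlation.

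Among cell type lists that did not pass at 4 weeks, the medians were 0.14 for macrophage, 0.30 for T cell, -0.39 for B cell, -0.14 for endothelial, 0.01 for mural (its test pointed down) and -0.14 for blood markers. Jchain (-1.09) of the B cell list passed adjusted over the list alone, as did the co-chaperone gene Bag3 (0.94), the glycolytic Pfkm (0.84) and Xist (-9.62), all in lists that did not pass. Antioxidant response genes (median -0.02, mean 0.02) and the 5 sex-linked genes (median 0.79, mean -1.10) differed in sign between median and mean.

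Of the 26 markers tested at 4 weeks, 0 passed, with 16 above 0. The heat-producing uncoupling protein Ucp1 measured 1150 ± 1330 CPM in libraries labelled KO and 1180 ± 538 in Flox (SD, n = 3 each; log2 difference -0.03), and the adipocyte hormone Adipoq 334 ± 83.3 and 334 ± 117 CPM (0.00). The groups lay apart for 4 markers. These were the proteasome subunit Psmd1 (128 ± 19.1 against 184 ± 18.6 CPM; -0.53), the endoplasmic reticulum chaperone Hspa5 (552 ± 82.1 against 377 ± 65 CPM; 0.55), Hmox1, which breaks down heme (0.33), and the NRF1 relative Nfe2l3 (1.32).

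With edgeR, 0 of 20465 genes passed at 4 weeks (smallest adjusted p = 0.454). At an unadjusted p under 0.05 there were 2043 genes (1172 higher, 871 lower) where 1023 were expected, and 17.1% of genes had groups that lay apart, against 10% by chance. DESeq2 called 256 genes (193 higher, 63 lower) and limma-voom 0. Zfp949 was the 1 gene called with no filter (1.96, adjusted p = 0.048) and with all 12 libraries in the fit (1.97, adjusted p = 0.0391), and without KO replicate 1 the count was 1764 (921 higher, 843 lower). The muscle and immediate early calls held without each library in turn, with the muscle median at 0.97 without KO replicate 2. Without Flox replicate 1 the white adipocyte median was -0.25. Without Flox replicate 3 the medians were -0.25 for proteasome, 0.44 for p53 and 2.47 for neutrophil genes. Without KO replicate 1 they were -0.34 for proteasome and 0.55 for p53 genes. With each library left out in turn the neutrophil median ranged from 0.55 to 2.47. Without Flox replicate 1 the proteasome (adjusted p = 0.138), p53 (0.0728), matrix (0.394), neutrophil (0.189) and progenitor (0.0553) calls ended. Without KO replicate 1 the matrix (0.219), progenitor (0.114), Schwann cell (0.441) and white adipocyte (0.125) calls ended. Without KO replicate 2 the proteasome (0.083), matrix (0.083) and neutrophil (0.234) calls ended, and without KO replicate 3 the p53 and progenitor calls (0.0531 each). Without Flox replicate 3, 18 lists passed. With the muscle score as covariate the proteasome median turned to 0.06 (adjusted p = 0.74), the matrix median to 0.07 (0.988) and the neutrophil median to -0.62 (0.063), and the p53 call ended (0.195). The muscle score itself set the labels apart at this age, so the covariate takes up part of any label difference. These changes therefore cannot show muscle as the source. Without both Flox libraries with Xist reads the Schwann cell call ended (0.0778).

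At 14-16 weeks, macrophage markers were higher in libraries labelled KO, with 24 of 24 above 0 and a median log2 difference of 2.02. Gpnmb, a glycoprotein of lipid-laden macrophages, measured 206 ± 309 against 1.97 ± 0.867 CPM (SD, n = 3 each; log2 difference 6.70), and the lipid receptor Trem2 18.4 ± 22.5 against 1.31 ± 0.414 CPM (3.82). Extracellular matrix genes (median 1.27, 30 of 34 above 0) and lysosome genes (0.63, 24 of 26 above 0) were higher too. Examples were Mmp12, the elastase of macrophages (5.40), and Atp6v0d2, a subunit of the proton pump of lysosomes (4.95). All 3 lists rose by camera (adjusted p = 9.79e-12, 5.5e-09 and 5.01e-07) and were lost at adjusted p = 0.769 with an estimated correlation. Over all genes 0 members passed, and adjusted over the list alone Gpnmb and Trem2, Mmp12 and Atp6v0d2 did. One library stood apart: Gpnmb measured 38.6, 562 and 15.9 CPM in KO replicates 1, 2 and 3. Without KO replicate 2 the medians were 0.57, 0.34 and 0.24, and all 3 lists still passed (adjusted p = 2.12e-10, 3.39e-05 and 7.85e-05).

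Nuclear-coded respiratory chain genes were lower at 14-16 weeks in libraries labelled KO, with 4 of 73 above 0 and a median log2 difference of -0.96. Cox7a1, a subunit of cytochrome c oxidase, measured 241 ± 135 against 545 ± 88.4 CPM (SD, n = 3 each; -1.17). The 13 mitochondrially coded respiratory chain genes all lay below 0 (median -0.93). Proteasome subunits (-0.32, 5 of 40 above 0), endothelial markers (-0.89, 1 of 17 above 0) and blood markers (-1.37, 0 of 6 above 0) were lower as well. The endothelial receptor Kdr measured 231 ± 91.8 against 508 ± 191 CPM (-1.14), and the globin genes Hbb-bs (-1.49) and Hba-a1 (-1.23) and the heme synthesis enzyme Alas2 (-1.34) were among the 6 blood markers that passed adjusted over the list alone. Immediate early genes lay below 0 in 20 of 22 cases (median -1.30), with Egr1 (-3.80) and Nr4a1 (-3.46) among the 9 that passed adjusted over the list alone. These 6 lists fell by camera (adjusted p = 1.19e-30, 3.96e-07, 1.77e-06, 1.83e-09, 2.22e-06 and 1.19e-12), and each was lost at adjusted p = 0.769 with an estimated correlation. All 40 ribosomal protein genes lay below 0 (-0.37, adjusted p = 5.01e-07; adjusted p = 0.838 with an estimated correlation), with a median of -0.24 without KO replicate 2 and -0.60 without KO replicate 3. The blood median was -0.87 without Flox replicate 1. The mitochondrial share of reads was 3.12% in KO replicate 2, against 11.2% and 9.42% in KO replicates 1 and 3 and 10.1% to 14.1% in Flox. Without that library the medians were -0.63 for nuclear-coded and -0.50 for mitochondrially coded genes, and both lists still passed (adjusted p = 7.48e-22 and 0.000209).

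**Figure D1:**
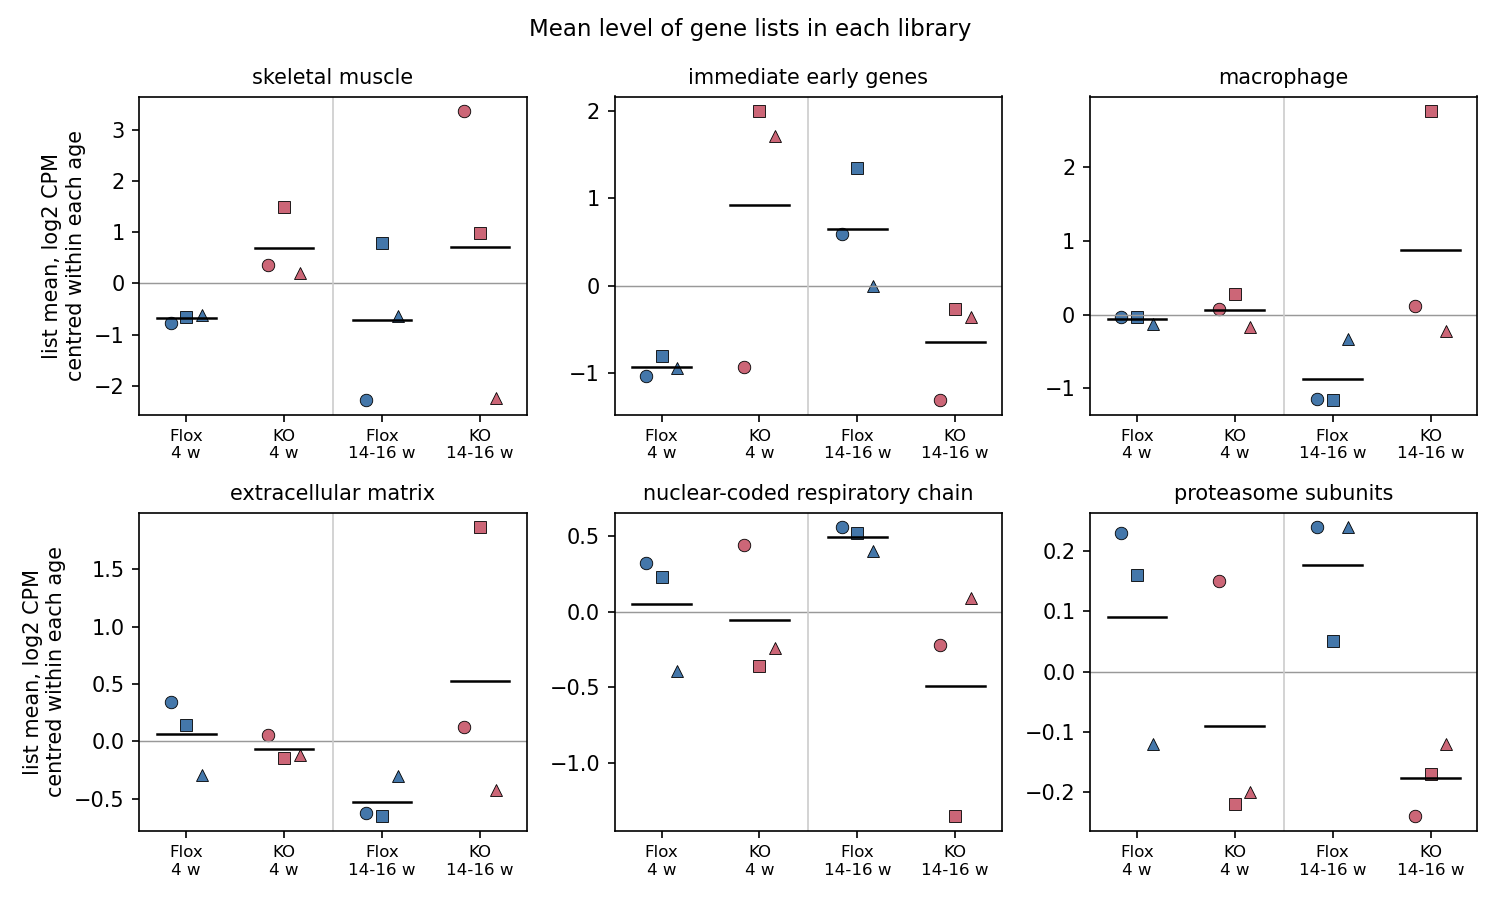
Mean log2 CPM of the members of 6 gene lists in each of the 12 libraries, centred within each age (vertical axis, log2 CPM), by group (horizontal axis); each point is 1 library, its shape gives the replicate number and the bar is the group mean. At 4 weeks the muscle values of the libraries labelled KO (0.35, 1.49 and 0.21) all lie above those of Flox (-0.77, -0.66 and -0.62), and at 14-16 weeks the macrophage value of KO replicate 2 stands apart.

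Skeletal muscle markers rose as a list at 14-16 weeks as well (median log2 difference 1.82, 23 of 23 above 0, adjusted p = 2.9e-05; adjusted p = 0.838 with an estimated correlation). Adjusted over the list alone the slow-fibre genes Myh7 (9.24), Tnnt1 (4.92) and Tnnc1 (4.23) passed. Myh7, the slow myosin heavy chain, measured 471 ± 681 CPM against 0.781 ± 0.803 (SD, n = 3 each). The muscle score was 3.37, 0.99 and -2.23 in the libraries labelled KO and -2.28, 0.79 and -0.64 in Flox, and without KO replicate 1 the list's median was -0.10 (adjusted p = 0.64) and without Flox replicate 2 it was 3.13. Per 1000 reads of the fast myosin gene Myh4 there were 95.4, 58.3 and 128 Myh7 reads in the libraries labelled KO and 1.94, 0.882 and 0.406 in Flox.

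Further lists that passed at 14-16 weeks were unfolded protein response (median 0.38, 19 of 20 above 0, adjusted p = 0.000842), fatty acid oxidation (-0.35, 5 of 23 above 0, 0.00329), T cell (0.86, 13 of 14 above 0, 0.00329), adipocyte progenitor (1.21, 13 of 16 above 0, 0.0256), general adipocyte (-0.23, 6 of 18 above 0, 0.0316) and pyroptosis genes (0.73, 9 of 12 above 0, 0.0486). These were lost at adjusted p = 0.838 with an estimated correlation. Cell cycle (1.06, 25 of 27 above 0) and interferon response genes (0.98, 24 of 25 above 0) passed at adjusted p = 0.00355 each and were lost at adjusted p = 0.861 with an estimated correlation. Adjusted over the list alone 0 members of these 8 lists passed. All 8 calls ended without KO replicate 2, where the medians were 0.17 for unfolded protein response (adjusted p = 0.0518), -0.13 for fatty acid oxidation (0.485), 0.20 for T cell (0.181), -0.05 for progenitor (0.834), 0.03 for general adipocyte (0.834), -0.01 for pyroptosis (0.902) and -0.13 for cell cycle genes (0.139), and the interferon list passed the other way (-0.40, adjusted p = 0.00724). Without Flox replicate 1 the pyroptosis (0.242) and interferon (0.284) calls ended, without Flox replicate 2 the pyroptosis call (0.14), and without Flox replicate 3 the fatty acid oxidation (0.109), general adipocyte (0.0894) and progenitor (0.226) calls. The T cell median was 1.30 without Flox replicate 3 and the fatty acid oxidation median -0.65 without KO replicate 1. The general adipocyte median was -0.14 and -0.11 without Flox replicates 2 and 3, and -0.63 without KO replicate 3.

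Among cell type lists that did not pass at 14-16 weeks, the medians were -0.49 for neutrophil, -0.11 for mural, 0.16 for Schwann cell, -0.08 for white adipocyte (mean 0.00) and -0.08 for B cell markers, whose mean (0.33) and test pointed up. Lipogenesis (median -0.07, mean 0.08), glycolysis (-0.03 and 0.03) and antioxidant genes (-0.05 and 0.06) also differed in sign between median and mean, as did the 5 sex-linked genes (0.01 and -0.13), and the circadian clock list (-0.05) had a test that pointed up.

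Of the 26 markers tested at 14-16 weeks, 0 passed, with 11 above 0. Ucp1 measured 1380 ± 903 CPM in libraries labelled KO and 2930 ± 2390 in Flox (SD, n = 3 each; log2 difference -1.08), and Adipoq 569 ± 225 and 598 ± 102 CPM (-0.07). Groups lay apart for Trem2, for the collagen gene Col1a1 (273 ± 365 against 37.4 ± 7.2 CPM; 2.87), and for the proteasome subunit Psmb5 (25 ± 0.583 against 37.2 ± 6.88 CPM; -0.57).

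With edgeR, 0 of 17962 genes passed at 14-16 weeks (smallest adjusted p = 0.569). At an unadjusted p under 0.05 there were 1475 genes (834 higher, 641 lower) where 898 were expected, and 12.9% of genes had groups that lay apart, against 10% by chance. DESeq2 called 76 genes (60 higher, 16 lower) and limma-voom 0. Without KO replicate 2, Mmp12 passed (3.96, adjusted p = 0.0376), and with the muscle score as covariate Myh7 (6.28) and Mhrt (6.32), an antisense transcript of the Myh7 locus, passed at adjusted p = 0.0268 each.

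Zfp949 and P2rx6 passed when the KO minus Flox difference was averaged over both ages, a comparison chosen after the data were seen. Zfp949, a zinc finger gene (GRCm38, chromosome 9, 88548020 to 88571061), measured 70.9 ± 11.6 against 18.2 ± 2.62 CPM at 4 weeks and 34.6 ± 9.55 against 13.9 ± 0.584 CPM at 14-16 weeks (SD, n = 3 each; mean log2 difference 1.64, SE 0.16, adjusted p = 0.00624). P2rx6, an ATP-gated channel subunit (chromosome 16, 17561885 to 17577800), measured 0.71 ± 0.338 against 3.76 ± 0.596 CPM and 0.841 ± 0.2 against 4.37 ± 1.48 CPM (-2.39, SE 0.29, adjusted p = 0.0249). P2rx6 was chosen after its values were seen, as its level lay under the rule's minimum. At both ages the groups lay apart for both genes. Of 19140 genes, 2565 had an unadjusted p under 0.05, DESeq2 called 83 (51 higher, 32 lower) and limma-voom the same 2. With no filter, Nfe2l1 (1.40) and Kng1 (1.86), which encodes the plasma protein kininogen, passed as well (adjusted p = 0.0364 each). With a fold change of 1.5 as the null 0 passed. With the replicate block 0 passed as well, and whether replicate numbers pair the samples is not known.

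Without each library in turn, Zfp949 passed in 11 of 12 fits and P2rx6 in 5 of 12, with log2 differences from 1.51 to 1.71 and from -2.60 to -2.25. Without Flox replicate 2 at 14-16 weeks 0 genes passed (Zfp949 adjusted p = 0.0576). Zfp949 alone passed without Flox replicate 1 at 14-16 weeks (adjusted p = 0.0438), Flox replicate 2 (0.0468), Flox replicate 3 (0.0237), KO replicate 2 (0.0335) or KO replicate 3 (0.0346) at 4 weeks, or KO replicate 1 at 14-16 weeks (0.0174). The count was 5 without Flox replicate 1 at 4 weeks, where Xist, Tsix and Gm26992 joined, 3 without KO replicate 2 at 14-16 weeks, where Kng1 joined, 32 without KO replicate 1 at 4 weeks and 27 without KO replicate 3 at 14-16 weeks. Kng1 and Eif4a2, a translation initiation factor, lie beside Adipoq on chromosome 16. They measured 15.7 ± 7.46 against 1.67 ± 0.183 CPM (3.23) and 479 ± 90.1 against 225 ± 18.8 CPM (1.09) at 4 weeks, with log2 differences of 0.50 and 0.53 at 14-16 weeks. Both were chosen after their values were seen. Neither passed at either age in edgeR with all libraries, while at 4 weeks DESeq2 called both (adjusted p = 1.82e-10 for Kng1 and 0.00267 for Eif4a2), as did edgeR without KO replicate 1 (0.0188 and 0.0114).

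**Figure D2:**
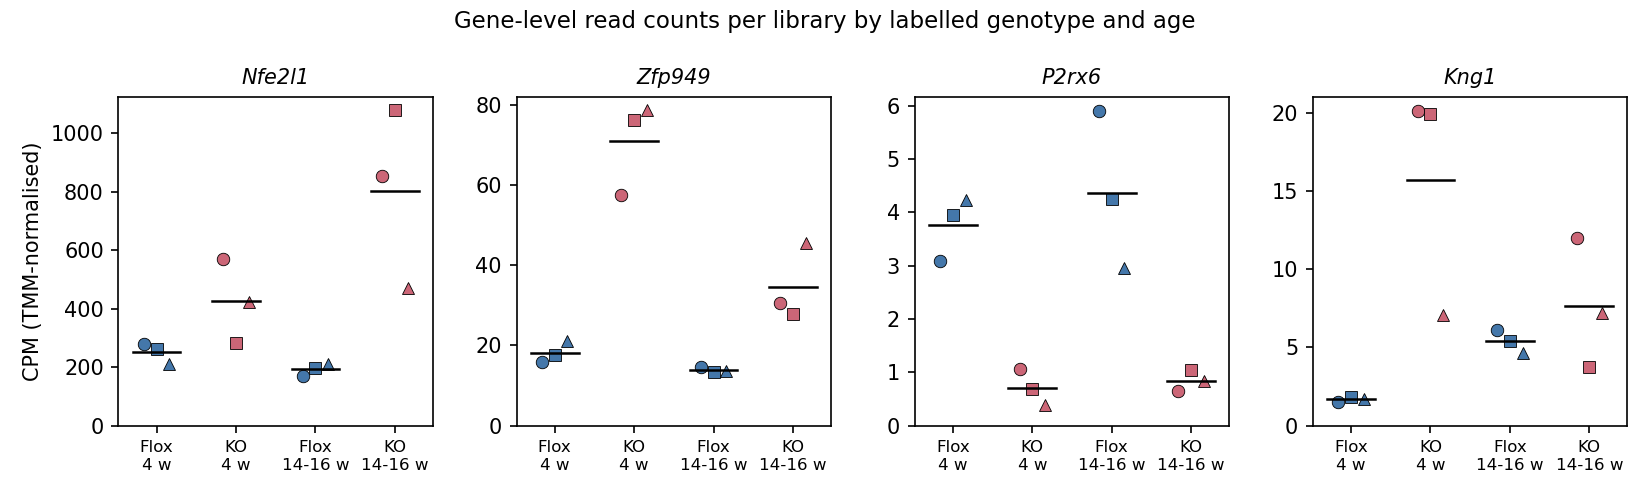
CPM on TMM-scaled library sizes (vertical axis) of Nfe2l1, Zfp949, P2rx6 and Kng1 in each of the 12 libraries by group (horizontal axis); each point is 1 library, its shape gives the replicate number and the bar is the group mean. Nfe2l1 and Zfp949 are higher and P2rx6 is lower in all libraries labelled KO than in the Flox libraries of the same age, and Kng1 is so at 4 weeks.

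**Figure D3:**
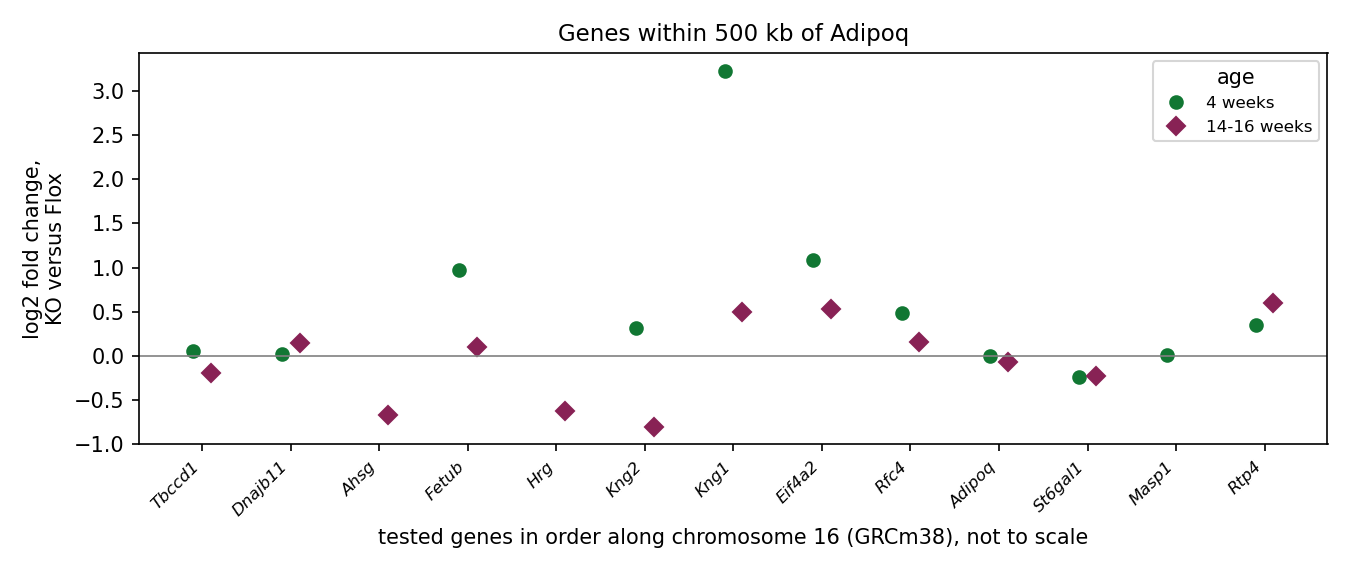
Log2 difference between libraries labelled KO and Flox libraries (vertical axis) at 4 weeks and at 14-16 weeks for genes within 500 kb of Adipoq. Each point is 1 gene at 1 age, in order along chromosome 16 of GRCm38 (horizontal axis, not to scale). Of the 22 genes tested at either age, small RNA, predicted and unnamed genes are not drawn. Among these, Snora81 (1.86) and Snord2 (1.38) lay above 0 and BC106179 (-0.57) below 0 at 4 weeks. Of the genes drawn, Kng1 (3.23) and Eif4a2 (1.09) stand highest at 4 weeks, followed by Fetub (0.97), and Adipoq itself lies at 0.00 and -0.07.

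Across the 16564 genes tested at both ages, log2 differences between the labels correlated weakly (Pearson r 0.18, Spearman rho 0.20 across genes, which are not independent replicates), and 57.9% had the same sign. No gene passed at both ages in edgeR. DESeq2 called 7 genes in the same direction at both ages where 0.4 were expected by chance. These were P2rx6, Zfp949, the muscle genes Myh6, Myh7 and Tnnc1, the antisense transcript Mhrt and the predicted gene Gm29015. Mhrt and Myh7 overlap on chromosome 14, and Gm29015 had nearly the log2 differences of Myh7 (1.42 and 9.62 against 1.41 and 9.27). Whether these share reads was not tested. As muscle genes can also vary together, the 7 do not count as 7 independent genes against the number expected. A further 6 were called in opposite directions (0.3 expected). At an unadjusted p under 0.05, 135 genes shared their direction (71.5 expected) and 51 had opposite directions (68.9 expected), and at p under 0.01 these counts were 11 (1.1 expected) and 6 (1.1 expected). The 11 include the 7 genes that DESeq2 called, with the same limit.

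The interaction asks whether the difference that goes with the KO label changes between the ages. Immediate early genes differed most, with all 21 below 0 and a median difference of -3.09 on the log2 scale, as they were higher at 4 weeks and lower at 14-16 weeks in libraries labelled KO. Fosb (-8.25), Nr4a1 (-6.83) and Nr4a2 (-4.00) were among the 15 members that passed adjusted over the list alone. Macrophage (1.91, 24 of 24 above 0), extracellular matrix (1.69, 29 of 33 above 0) and adipocyte progenitor lists (1.5, 14 of 16 above 0) had larger differences at 14-16 weeks, with Gpnmb (7.16) and Mmp12 (5.77) passing adjusted over their lists alone. Nuclear-coded respiratory chain genes (-0.86, 2 of 72 above 0), neutrophil (-2.18, 0 of 9 above 0), endothelial (-0.71, 1 of 17 above 0) and blood markers (-1.30, 0 of 8 above 0) went the other way. All 8 lists passed by camera (adjusted p = 5.17e-26, 1.4e-10, 2.88e-11, 0.000743, 8.1e-17, 0.000216, 0.000109 and 0.000856). The first was lost at adjusted p = 0.151 with an estimated correlation and the other 7 at adjusted p = 0.655 with an estimated correlation. Immediate early genes stood apart in KO replicates 2 and 3 at 4 weeks, where Fos measured 282 and 205 CPM, and the macrophage genes in KO replicate 2 at 14-16 weeks. Without that library the medians were 0.38 for macrophage, 0.65 for matrix, 0.24 for progenitor, -0.48 for nuclear-coded respiratory chain and -0.47 for endothelial genes. Without Flox replicate 1 at 14-16 weeks they were -0.40 for endothelial, -0.82 for blood and -1.45 for neutrophil markers. Without KO replicate 1 at 4 weeks the nuclear-coded median was -0.55, and the neutrophil median was -3.39 without Flox replicate 3 and -1.44 without KO replicate 2 at 4 weeks.

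Lysosome genes (0.71, adjusted p = 4.07e-05) and Schwann cell markers (0.83, adjusted p = 0.0237) also passed in the interaction, both lost at adjusted p = 0.655 with an estimated correlation. Ribosomal protein genes (-0.53, adjusted p = 3.67e-10) were lost at adjusted p = 0.67 with an estimated correlation. Without KO replicate 2 at 14-16 weeks the lysosome median was 0.27 and the ribosomal median -0.35. Mitochondrially coded respiratory chain genes (-0.76, adjusted p = 0.0023), cell cycle genes (0.92, 0.0418) and proteasome subunits (-0.19, 0.0479) were lost at adjusted p = 0.854 with an estimated correlation. The cell type medians that did not pass were 0.55 for T cell, 0.09 for B cell, 0.02 for mural (its test pointed down), 0.25 for skeletal muscle and 0.52 for white adipocyte markers. Adjusted over the list alone, Atp6v0d2 (5.10), Egr2 (-4.99) and Mbp (0.89) passed in lists that did, and Jchain (3.90), Myh7 (7.82), Xist (8.79) and Tnfrsf10b (-2.82) in lists that did not. Median and mean or test differed in sign for the ubiquitin (0.15 and -0.10), integrated stress response (0.06 and -0.14), lipolysis (-0.02 and 0.01) and sex-linked lists (-0.95 and 0.97).

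With edgeR, 0 of 19140 genes passed the interaction (smallest adjusted p = 0.545), and 0 of 27 markers did. At an unadjusted p under 0.05 there were 1335 genes (702 higher, 633 lower) where 957 were expected. DESeq2 called 49 (19 higher, 30 lower) and limma-voom 0. The count was 46 (2 higher, 44 lower) without KO replicate 1 at 4 weeks. It was 3 without Flox replicate 1 at 4 weeks, namely Xist (9.38), its antisense Tsix (10.24) and Gm26992 (7.97). In that fit both remaining Flox libraries at 4 weeks were those with many Xist reads. Of the 14 lists, 8 passed without each library in turn. The proteasome call ended without KO replicate 1 (adjusted p = 0.716) or Flox replicate 3 (0.474) at 4 weeks, and without Flox replicate 1 (0.105), Flox replicate 3 (0.196), KO replicate 1 (0.0984) or KO replicate 2 (0.0752) at 14-16 weeks. The mitochondrially coded call ended without KO replicate 1 (0.456) or Flox replicate 3 (0.135) at 4 weeks and without KO replicate 2 at 14-16 weeks (0.201). The cell cycle call ended without KO replicate 1 (0.275) or Flox replicate 3 (0.229) at 4 weeks and without Flox replicate 1 (0.106), Flox replicate 3 (0.0646) or KO replicate 2 (0.0826, median -0.26) at 14-16 weeks. The Schwann cell call ended without KO replicate 1 (0.279) or Flox replicate 3 (0.135) at 4 weeks and without Flox replicate 1 (0.0799), Flox replicate 3 (0.0678), KO replicate 2 (0.077) or KO replicate 3 (0.108) at 14-16 weeks. The blood call ended without Flox replicate 1 (0.115) and the progenitor call without KO replicate 2 (0.12), both at 14-16 weeks. Without KO replicate 1 at 14-16 weeks, 22 lists passed.

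Between 4 and 14-16 weeks in Flox, the 4 genes that the naming rule took on the higher side encode plasma and milk proteins. Those it took on the lower side include the slow myosin Myh7. No gene list was tested between the ages. The albumin gene Alb (log2 difference 9.36) measured 34.6 ± 2.07 CPM at 14-16 weeks against 0.047 ± 0.051 at 4 weeks (SD, n = 3 each; adjusted p = 3.18e-05), and the apolipoprotein gene Apoa1 17.9 ± 2.83 against 0.0414 ± 0.0422 CPM (8.59, adjusted p = 3.18e-05). The milk protein gene Csn3 and the fibrinogen gene Fgb measured 14.6 ± 1.48 and 11.1 ± 2.43 CPM at 14-16 weeks and had 0 reads in each Flox library at 4 weeks. Reads of 12 liver markers, Alb and Fgb among them, summed to 2398 to 2901 in every library at 14-16 weeks of either label (coefficient of variation 7.84%) and to 12 to 43 at 4 weeks. Whether these reads came from the tissue was not tested. Myh7 (-8.51, adjusted p = 0.00748), its antisense Mhrt (-8.60, 0.00486), the transcription factor gene Mef2b (-6.97, 0.00143) and the matrix protease gene Mmp11 (-5.69, 3.18e-05; 2.05 ± 1.02 against 105 ± 18.2 CPM) were lower at 14-16 weeks. Of the 27 markers, the chemokine Ccl2 (4.73, adjusted p = 0.0267) and Nfe2l3 (2.52, adjusted p = 0.0201) were higher. Both calls ended without Flox replicate 1 (adjusted p = 0.0796 and 0.0607), 2 (0.117 and 0.1) or 3 (0.113 and 0.0794) at 4 weeks, and without Flox replicate 3 at 14-16 weeks (0.132 and 0.0955).

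In Flox, 1342 of 19140 genes passed (769 higher, 573 lower), with 4690 at an unadjusted p under 0.05, and DESeq2 called 2598. With a fold change of 1.5 as the null 456 passed. The count was 624, 385 and 400 without Flox replicates 1, 2 and 3 at 4 weeks, and 698 and 483 without Flox replicates 2 and 3 at 14-16 weeks. The gene model differed between the tables for 396 of the 1342 genes, and with genes of the same model alone 791 passed. Pgm1 (-4.09) and Pgm2 (3.97) show the limit, as the symbol Pgm1 lay on chromosome 4 in the 4-week table and on chromosome 5 in the 14-16-week table. Age and table cannot be told apart, and the Xist reads of Flox replicates 2 and 3 at 4 weeks add a difference in sex.

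Between 4 and 14-16 weeks in libraries labelled KO, the named genes that were higher include macrophage markers and immunoglobulin genes, and those that were lower include immediate early genes, with no list tested. Of the markers, the macrophage genes Adgre1 (log2 difference 3.63, adjusted p = 0.0274) and Trem2 (3.31, 0.0134) and the chemokine Ccl2 (3.40, 0.0401) were higher, and Cdkn1a, a brake on the cell cycle, was lower (-2.67, 0.00952). The largest differences under the naming rule were Alb (9.83, adjusted p = 3.85e-05), with the same doubt about its source as in Flox, and 3 immunoglobulin constant genes. These were Ighg1 (8.54, adjusted p = 0.0124), Ighg2c (7.19, 0.00224) and Ighg2b (6.74, 0.00763). On the lower side the rule took Egr3 (-8.23, 0.00782), Fosb (-7.34, 0.00351), Nr4a1 (-6.21, 0.00473) and Mef2b (-6.17, 0.00172). Ighg2c measured 13.9, 179 and 8.74 CPM in KO replicates 1, 2 and 3 at 14-16 weeks, and Nr4a1 7.02 ± 8.54 CPM against 517 ± 389 at 4 weeks (SD, n = 3 each). Nfe2l1 was higher at 14-16 weeks as well (1.05, adjusted p = 0.044). The Nfe2l1 call held in 2 of 12 fits without 1 library (highest adjusted p = 0.16) and the Ccl2 call in 4 of 12 (0.131). Without KO replicate 2 or 3 at 4 weeks the Adgre1 (adjusted p = 0.0933 and 0.107), Trem2 (0.058 and 0.0628) and Ighg1 calls (0.0569 and 0.0606) ended, and without KO replicate 2 at 14-16 weeks the Adgre1 call (1.11, 0.204).

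In libraries labelled KO, 3426 of 19140 genes passed between the ages (1825 higher, 1601 lower), with 6689 at an unadjusted p under 0.05, and DESeq2 called 4979. With a fold change of 1.5 as the null 1105 passed. The count was 1024 and 1081 without KO replicates 2 and 3 at 4 weeks and 2171 without KO replicate 2 at 14-16 weeks. The gene model differed between the tables for 821 of the 3426 genes, and age and table cannot be told apart here either. The interaction is the test of whether the ages differ more under 1 label than under the other, and it called 0 genes in edgeR.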

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

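The tests on exchanged labels, sex, the Adipoq region, muscle, the share of adipocytes and left-out libraries were chosen after the results were seen, and the test on mitochondrial transcripts and the splits for the mean over both ages were added after the data were seen but set before their own results, while the other counts over splits were chosen before. Each list named first here was singled out because its KO minus Flox difference differed between the ages in the interaction test, and all values are medians on the log2 scale.

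The differences between the ages were -0.19 for proteasome subunits, -0.86 for nuclear-coded and -0.76 for mitochondrially coded respiratory chain genes, and -0.53 for ribosomal protein genes. They were 1.69 for extracellular matrix, 0.92 for cell cycle and 0.71 for lysosome genes. For cell type markers they were 1.91 for macrophage, -2.18 for neutrophil, -0.71 for endothelial, 1.5 for adipocyte progenitor, 0.83 for Schwann cell and -1.30 for blood markers, and for immediate early genes -3.09. Without KO replicate 2 at 14-16 weeks the macrophage, matrix and progenitor values fell to 0.38, 0.65 and 0.24. Of 100 splits of the libraries, 89 gave at least as many lists as the 14 called (highest other 25), so chance cannot be excluded for their number.

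At 4 weeks, the split of Flox replicate 3 and KO replicates 2 and 3 against the other 3 libraries called 3091 genes, against 0 for the labels (10 of 10 splits gave at least 0), which points to a structure of the samples. An exchange of labels between Flox replicate 3 and KO replicate 1 is argued against by Nfe2l1, 2.7 times as high in KO replicate 1, as the separate libraries of 14-16 weeks show the gene higher under the KO label, whatever the reason. Of 47 genes chosen at 14-16 weeks (unadjusted p under 0.01) and apart between the other 4 libraries of 4 weeks, 30 lay with the labels in these 2 libraries and 17 against them. These genes are not independent of each other. Under 0.001 both genes, Nfe2l1 and P2rx6, lay with the labels, where Nfe2l1 repeats the values already given. Sex is argued against because 2 of the 3 libraries on the side of Flox replicate 3 held more Ddx3y than Xist reads. Without mitochondrial genes, their nuclear copies and Rn18s, 3038 genes were still called. TMM scaling already limits what such genes do to the counts of others, so this cannot decide on a large mitochondrial share. Mitochondrially encoded genes took 11.5%, 9.7% and 13.5% of the reads in Flox replicates 1 and 2 and KO replicate 1. In Flox replicate 3 and KO replicates 2 and 3 the shares were 4.67%, 4.21% and 7.12%. What sets these 3 libraries apart stays open, and no biological explanation was tested because the labels name none.

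Zfp949, P2rx6 and the genes beside Adipoq form the second pattern. Sex of the Flox libraries is argued against for Zfp949 by its difference at 4 weeks of 2.15 without the 2 libraries with Xist reads, and muscle by its difference at 14-16 weeks of 1.42 with the muscle score as covariate. A candidate explanation for the neighbours of Adipoq is extra copies of that region carried by a recombinase transgene, but the labels do not name the driver. The mean difference of Kng1, Eif4a2 and Rfc4 at 14-16 weeks lay above that of 79.5% of runs of 3 neighbouring genes, too near the middle to decide. Kng1 also held 155, 140 and 138 reads in Flox at 14-16 weeks, against 73, 88 and 99 in the deeper libraries at 4 weeks. Liver marker reads, whose source was not tested, were likewise higher at 14-16 weeks. Whether such reads add to Kng1 was not tested, so its difference at that age cannot judge extra copies. Extra copies thus cannot be told apart from an effect of the label. An effect of Nfe2l1 itself on these genes stays open and untested.

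The lists called at 14-16 weeks form the third pattern, and all 19 calls were lost with an estimated correlation (smallest adjusted p = 0.769). Without KO replicate 2, whose loss ended more calls than that of any other library, 11 lists stayed in their direction. Some were about as large (proteasome -0.34, immediate early genes -1.43) and some smaller (macrophage 0.57). With each library left out in turn, 10 calls held in every fit, so no single loss ended them. A single library as the source of all the calls, or of these 10, cannot be judged this way. Other splits of the same libraries called 15 to 27 lists, so a list can pass for reasons other than the label. Of the 8 lists that did not stay without KO replicate 2, interferon response passed the other way (-0.40, adjusted p = 0.00724). For these 8 and for skeletal muscle, whose call ended without KO replicate 1, a single library as the source stays open. A lower share of adipocytes cannot be told apart from other sources. The macrophage minus endothelial score differed by 2.60 (SE 1.34) between the labels, within 2 SE of 0, and it holds no adipocyte marker. By itself a lower share would raise markers of the other cell types, but macrophage markers were higher (2.02) and endothelial markers lower (-0.89). The general adipocyte scores were 0.10, -0.94 and 0.23 in libraries labelled KO and 0.22, 0.19 and 0.20 in Flox, so low mainly in KO replicate 2. More macrophages, fewer vessels or a change within cells that goes with the label may each contribute and were not tested.

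For lists at 14-16 weeks, 5 of 10 splits gave at least the 19 called (highest other 27). At 4 weeks 9 of 10 splits gave at least the 9 lists called (highest other 25). Chance cannot be excluded for either number, and 10 splits are too few for a share under 0.05. For genes at 14-16 weeks the labels called 0 (highest other 0), so 10 of 10 splits gave at least as many by construction. For age in Flox and in libraries labelled KO, 1 of 10 splits each gave as many genes, the real one (1342 and 3426, highest other 0 for both), again too few splits. For the interaction the labels called 0 genes, so 100 of 100 splits gave at least as many by construction (highest other 384). For the mean over both ages 6 of 100 splits gave at least the 2 genes (highest other 384), so chance cannot be excluded for that count. Apart from the real one, these splits all set Flox replicate 3 and KO replicates 2 and 3 apart at 4 weeks. That split called 3091 genes by itself, so the share reflects this structure of the samples and does not measure chance alone.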

How the results depend on the processing

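The fits with the muscle score, without the 2 Flox libraries with Xist reads, with genes of the same model, with unadjusted p-values shared by both ages, and every value of the mean over both ages were chosen after the data were seen. Counts of genes moved with the tool. DESeq2 called 256 genes at 4 weeks, 76 at 14-16 weeks, 49 in the interaction, 2598 for age in Flox and 83 for the mean, and it called Nfe2l1 at 14-16 weeks (2.07) and in the mean (1.41). The overlap of the ages was 0 genes, 7 by DESeq2, 135 at an unadjusted p under 0.05 and 11 under 0.01. With a fold change of 1.5 as the null the counts were 456 for age in Flox, 1105 for age in KO and 0 for the mean, where fewer genes can pass by construction. With no filter they were 1 at 4 weeks and 4 for the mean. All 12 libraries in the fit gave 1 gene at 4 weeks, the muscle covariate 2 at 14-16 weeks, and genes of the same model 791 for age in Flox. The replicate block gave 118 genes for age in Flox, 91 for age in KO and 0 for the mean. Whether replicate numbers pair the samples stays open at 4 weeks, and at 14-16 weeks nothing pointed to it. Deviations of same-numbered libraries correlated at 0.50, -0.14 and 0.41 at 4 weeks and -0.01, -0.04 and -0.02 at 14-16 weeks. At these ages 3 of 6 and 0 of 6 libraries correlated best with their own number.

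Without each library in turn the counts ranged from 0 to 1764 genes at 4 weeks, 0 to 1 at 14-16 weeks, 0 to 46 in the interaction, 385 to 1991 for age in Flox, 1024 to 4526 for age in KO and 0 to 32 for the mean. Nfe2l1 ranged from 1.26 to 1.53 in the mean. Lists ranged from 6 to 18 at 4 weeks, 10 to 22 in the interaction, 13 to 21 at 14-16 weeks and 9 to 21 for the mean. Camera with an estimated correlation and fry each called 0 lists in all 4 comparisons. At 4 weeks 22 lists passed with the muscle covariate and 17 without the 2 Flox libraries with Xist reads. Of 951 values of the markers under alternatives, 849 kept direction and call and 96 changed sign with no call. Without KO replicate 1 at 4 weeks, Adrb3 (-1.35), Cdkn1a (1.71), Ddit3 (0.91), Gdf15 (3.05) and Prdm16 (-1.35) passed and Elovl3 reversed (-2.28, adjusted p = 0.0379), against a highest value of 0.54 without KO replicate 2. The cause was not tested for any of these moves except where construction is named. RLE and upper-quartile scaling, limma-voom, the stricter filter and mitochondrial genes left out kept every gene count within 1.5 times. With 3 libraries per group, most 2-fold changes were not recovered in the simulated data. Far larger real differences did not pass either, such as Myh7 (9.24) and Gpnmb (6.70) at 14-16 weeks. The simulated shares, with each gene drawn independently, thus do not show how many changes the real comparisons missed.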

Other observations

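The tests behind these values were all chosen after the data were seen, and the values carry no explanation. Reads of 12 liver marker genes summed to 12 to 43 per library at 4 weeks (coefficient of variation 39.5%) and to 2398 to 2901 at 14-16 weeks (7.84%). The milk protein gene Csn3 had 225 to 460 reads in each library at 14-16 weeks and 0 in each at 4 weeks. Myh7 reads per 1000 Myh4 reads were 310, 253 and 191 in Flox and 210, 157 and 156 in libraries labelled KO at 4 weeks, against 1.94, 0.882 and 0.406 and 95.4, 58.3 and 128 at 14-16 weeks.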
